A study of Homo sapiens with 2 samples.

How the data were processed

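Genomic DNA of SH-SY5Y cells exposed to DMSO or Mdivi-1 was converted with bisulfite after methyl capture with the SureSelectXT kit and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. RNA-seq named in the design text was not analysed here. The submitters' processing notes name the BSMAP aligner, with no version, and the hg19 build, and all coordinates below are hg19 positions from the deposited table. For each of 2773807 positions the authors deposited the methylated fraction and the coverage in each library, the difference of the fractions, a hyper or hypo mark, and gene, promoter and CpG island annotation. The coverage columns deposited by the authors are taken here as estimated counts, because a few are not whole, and the reason for this is not given in the sources used here. In the authors' deposited table, every position whose fraction differed by at least 0.2 carries a mark, with no filter on coverage.

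The control fractions did not correspond to whole reads at the deposited coverage, being whole for 33.3% of positions within a tolerance of 1e-06. They did so at every position once the coverage was multiplied by 1.23, the ratio of the median coverages of 37 and 30 reads, and rounded. This rescaling is read from the deposited values and is not stated in the sources used here. Whole methylated reads were recovered by searching for the count that this rescaling turns into the deposited fraction, and a single count was found for all but 47 control positions of whole coverage. In total 10798 positions (0.389%) were left out, 10751 of them for fractional coverage. The deposited fraction of the Mdivi-1 library was not rescaled.

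CpGs with at least 10 reads in both libraries were kept. Levels were means over CpGs in percent, and differences are Mdivi-1 minus control in percentage points. Single CpGs were compared by two-sided Fisher exact tests with Benjamini-Hochberg adjustment, calling an adjusted p under 0.05 with a difference of at least 20 points. Windows of 1 kb and promoters counted by a rule of size, with at least 5 CpGs, a mean difference of at least 10 points and 80% of CpGs in its direction. A gene's promoter CpGs were combined per chromosome, so a gene with several start sites can span many kilobases. Gene lists were compared with 10000 random lists matched on deciles of promoter methylation. Of 626 listed symbols, 612 matched the deposited annotation, 22 list entries through a synonym in the RefSeq gene table of assembly GRCh38.p14, which was used for names alone. With 1 library per group there is no test over genes or windows.

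Named were the 10 promoters of largest gain and the 10 of largest loss that met the rule, the 5 windows of each direction, DNM1L, up to 3 members of each list with the largest absolute difference, and the 5 called CpGs of smallest p in each direction, with ties broken by coverage and then position. Of the list members so chosen, 3 are not reported here. These rules, the lists, the tests and the first set of alternatives were fixed before the data were examined. That set held other coverage minimums, pooled reads, autosomes only, other sizes of difference, thinning to equal depth, removal of very deep CpGs, centring by level, other window sizes and CpG numbers, and other list statistics. Use of the deposited fractions or rescaled reads, inclusion of fractional coverage, exclusion of the X chromosome, and other ways of setting the level of a window were added after seeing the data.

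Counting errors came from binomial variances. Those for independent CpGs used the pooled level of each CpG. Those for fully shared reads used the mean level of the region over both libraries and its mean coverage. They treat the same reads as covering all its CpGs, each read being wholly methylated or wholly unmethylated. Equal-level libraries were drawn 20 times from the pooled level of each CpG at its real coverage, and 5 times for the Fisher test. Pooled levels of the mitochondrial positions and of nuclear positions left out for lack of recovered whole counts have 95% Wilson intervals. The scripts were tested on simulated data: recovery returned 100.0% of counts and none wrongly. The window rule found 52.5%, 99.5% and 100% of 200 windows changed by 10, 20 and 30 points among 123163. The list comparison placed 4.50% of 200 unshifted simulated lists outside the central 95%. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9.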

Results

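DNA methylation was measured in SH-SY5Y cells, an established human neuroblastoma line with sympathetic neuron-like properties, after exposure to Mdivi-1 or to its solvent DMSO. Mdivi-1 is a small molecule used to block mitochondrial fission and was described as an inhibitor of DRP1, the dynamin-related GTPase encoded by DNM1L. Each group held 1 library of bisulfite-converted, methyl-capture DNA, 2 libraries in all, so no difference below has a replicate check. After positions of fractional coverage were set aside, 2523690 CpGs had at least 10 reads in both libraries. Mean coverage of these CpGs was 39.7 reads in the control and 49.1 reads in the Mdivi-1 library. Errors given below cover the counting of reads, which may share a PCR origin, and not the variation between cultures.

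The first comparison addressed whether methylation differed across the captured genome. Mean CpG methylation was 42.6% in the control and 43.1% in the Mdivi-1 library, a difference of 0.460 percentage points with a counting error of 0.00452 points. Taking 1 kb blocks in place of single CpGs gave an error of 0.00679 points. CpGs above 90% made up 23.3% of the control and 25.4% of the Mdivi-1 library, whereas CpGs under 10% made up 42.0% and 42.0%. Such shares also depend on depth, which was lower in the control, and they were not compared at equal depth. The level was higher in the Mdivi-1 library on each of the 23 chromosomes with at least 100 CpGs, by 0.338 to 0.609 points. Across CpGs, which are not independent replicates, the libraries correlated with a Pearson r of 0.984. The root mean square difference per CpG was 7.41 points, against 7.17 points from read counting at equal levels.

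Across the CpG island classes, the difference was larger where the control level was higher. CpG islands, the CpG-dense stretches that often cover promoters, were at 28.9% and 29.2% in the control and Mdivi-1 libraries, a difference of 0.269 points over 963995 CpGs. Island shores differed by 0.463 points from a control level of 42.8%, island shelves by 0.586 points from 55.7% and CpGs outside these classes by 0.666 points from 56.1%. Among gene annotations, 3' UTRs had the largest difference, 0.705 points from a control level of 66.2%. The order did not follow the level throughout: intronic CpGs differed by 0.549 points from 46.5% and exonic CpGs by 0.526 points from 59.6%. Intergenic CpGs differed by 0.469 points. The smallest differences lay upstream of genes, at 0.228 points, and in 5' UTRs, at 0.191 points from a control level of 15.4%. Among 1 kb windows sorted by their mean level, those under 5% differed by 0.0410 points, those at 40 to 60% by 0.594 points, those at 85 to 95% by 0.994 points and those at 95% or more by 0.419 points. Sorting by the level of adjacent windows gave 0.233, 0.465, 0.853 and 0.748 points, so these values depended on the sorting. The value of the lowest group changed most in proportion. Groups sorted in that way hold other windows, whose own level can differ from that of their neighbours. Counting errors of all 13 annotation classes were far smaller than their differences, but the spread between cultures was not measured.

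**Figure D1:**
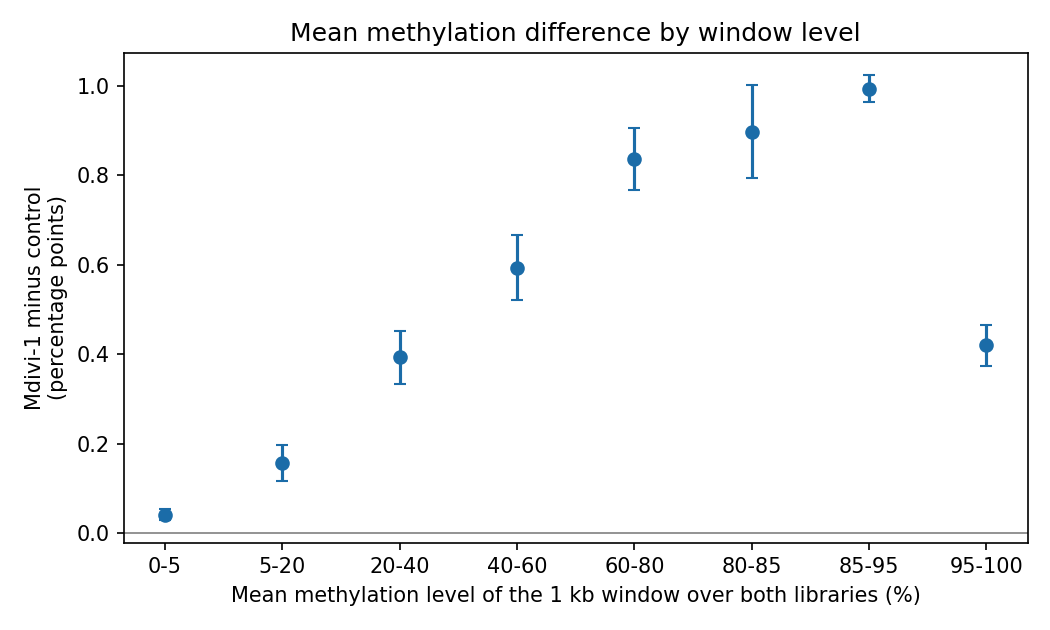
Mean methylation difference between the libraries (percentage points, Mdivi-1 minus control) of 1 kb windows grouped by their mean level over both libraries (%). Points are means over windows and bars are 95% intervals over windows. The difference goes from 0.0410 points in windows under 5% to 0.994 points at 85 to 95%. Both ends depend on the sorting. Windows whose adjacent windows were under 5% differed by 0.233 points, and those with adjacent windows at 95% or more by 0.748 points.

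The second comparison asked which 1 kb windows differed. A window counted when it held at least 5 CpGs, its mean CpG difference was at least 10 points and at least 80% of its CpGs differed in that direction. Of 123163 windows, 714 were higher and 460 were lower in the Mdivi-1 library, and 53 differed by at least 20 points. Most were intermediate in level, with 80.7% of them between 20 and 80%. Of all 123163 windows, 43335 lay in that range, where binomial counting error is also larger. At those levels 6.08% of X-chromosome windows met the rule, against 2.0% elsewhere. Equal-level draws also gave more such windows on the X chromosome, 0.810% against 0.531% with independent CpGs and 18.4% against 9.90% with fully shared reads, so part of this excess comes from counting. Libraries drawn at equal levels gave 279.6 such windows on average when CpGs were drawn independently, and 6357 when all CpGs of a window shared their reads. The observed 1174 windows lie between these values, so how many exceed counting error depends on how far CpGs shared reads and methylation states along them. Taking all reads as shared, 9 of them lay beyond their 95% counting interval and 1165 within it. Of all 123163 windows only 0.00893% lay beyond it, far fewer than a fitting 95% interval would leave out, so full sharing overstates the error. Among the windows named below, those of NVL, TREX2, ST8SIA1, LINC02370 and PCDHA12 lay beyond it. These were chosen for their size from the same reads, so this gives them no separate support.

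The window of largest gain lay in intergenic sequence 10927 bp from NVL, a nuclear AAA ATPase gene (chromosome 1, 224528769 to 224528876, hg19), at 24.2% in the control and 68.3% in the Mdivi-1 library over 9 CpGs. Its difference of 44.1 points has a counting error of 6.52 points for independent CpGs and 19.7 points for fully shared reads, at a mean coverage of 16.1 and 10.6 reads. A window 2526 bp from the exonuclease gene TREX2 (chromosome X, 152707615 to 152707679) was at 14.7% in the control and 51.6% in the Mdivi-1 library over 7 CpGs. An intronic window of ST8SIA1, which encodes the ganglioside GD3 synthase (chromosome 12, 22441058 to 22441642), was at 34.7% in the control and 67.5% in the Mdivi-1 library over 7 CpGs. An exonic window of TERT, the catalytic subunit of telomerase (chromosome 5, 1279484 to 1279547), was at 45.0% in the control and 77.3% in the Mdivi-1 library over 9 CpGs. The exonic window of TRIM72, a membrane repair gene (chromosome 16, 31230637 to 31230813), was at 31.1% in the control and 58.7% in the Mdivi-1 library over 11 CpGs.

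The window of largest loss lay 75795 bp from LINC02370 (chromosome 12, 131927877 to 131927936), at 71.9% in the control and 37.5% in the Mdivi-1 library over 5 CpGs, with counting errors of 6.96 and 15.6 points under independent and fully shared reads. A window 25421 bp from LINC01621 (chromosome 6, 80487825 to 80487961) was at 43.9% in the control and 12.3% in the Mdivi-1 library over 14 CpGs. An intronic island window of PAX7, a transcription factor of neural crest and muscle progenitors (chromosome 1, 19043648 to 19043674), was at 38% in the control and 6.82% in the Mdivi-1 library over 5 CpGs. An exonic window of the neuronal adhesion gene PCDHA12, which also overlaps LOC112267934 (chromosome 5, 140255010 to 140255108), was at 52.4% in the control and 22.8% in the Mdivi-1 library over 5 CpGs. An exonic island window of the semaphorin receptor gene PLXNB3 (chromosome X, 153038703 to 153038835) was at 73.5% in the control and 46.1% in the Mdivi-1 library over 9 CpGs. Mean coverage in the PAX7 window was 10 reads in the control and 11.8 in the Mdivi-1 library, the lowest depth allowed in the control.

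**Figure D2:**
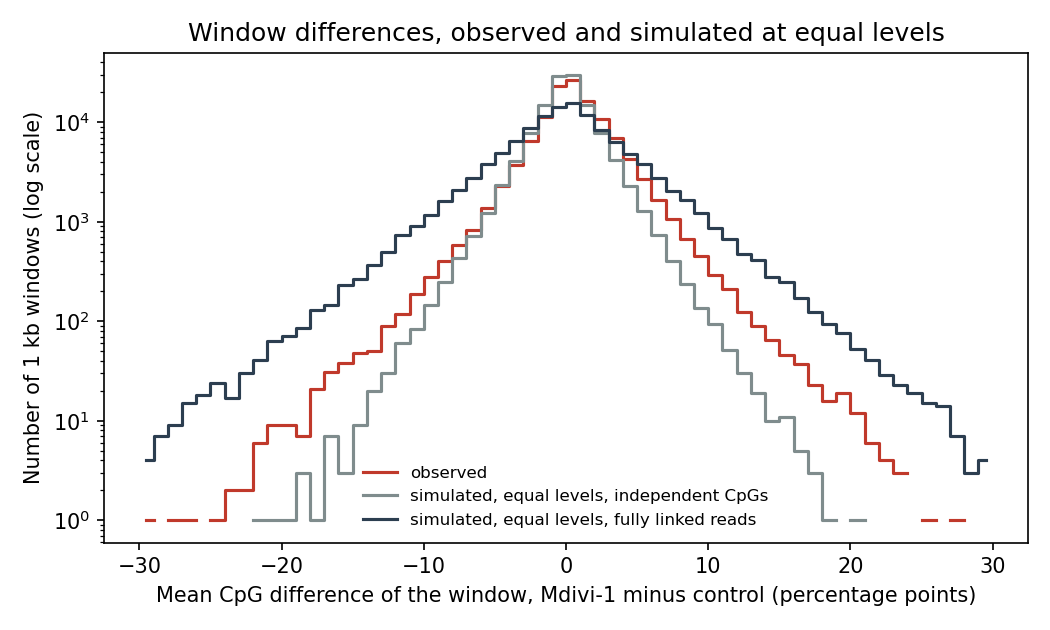
Number of 1 kb windows (log scale) by mean CpG difference (percentage points, Mdivi-1 minus control, from -30 to 30 in steps of 1) as observed and in 1 draw each of libraries simulated at equal levels with independent CpGs or fully shared reads. The observed curve lies outside the independent draw and inside the shared-read draw in both tails.

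Promoters were compared by the same rule of size, on CpGs that the deposited annotation assigns to a promoter. Of 23526 measured promoters, 34 were higher and 35 were lower in the Mdivi-1 library. The median promoter difference was 0.20 points, and 8269 promoters were under 10% in both libraries. Equal-level draws gave 15.4 promoters with independent CpGs and 618 with fully shared reads. Of the 69 promoters, 14 were on the X chromosome, 5 higher and 9 lower, as were 866 of the 23526 measured. All 14 were at 20 to 80%, where 2.53% of X-chromosome promoters met the rule, against 0.565% elsewhere. At those levels equal-level draws gave 0.289% against 0.140% with independent CpGs and 14.0% against 4.93% with fully shared reads. Part of this excess therefore comes from counting. Requiring 10 CpGs in place of 5 left 24 promoters, 9 higher and 15 lower. A minimum of 20 reads in place of 10 left 42, 14 higher and 28 lower.

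POU5F2, a POU-family transcription factor gene, had the largest promoter gain (chromosome 5, 93077317 to 93077697), with 69.7% in the control and 91.6% in the Mdivi-1 library over 6 CpGs. Its difference was 22.0 points, with counting errors of 5.44 and 12.9 points for independent and fully shared reads. The microRNA promoter MIR6881 was at 16.2% in the control and 37.1% in the Mdivi-1 library. CTCFL, the germline paralog of the insulator factor CTCF (chromosome 20, 56102521 to 56102602), was at 33.2% in the control and 49.0% in the Mdivi-1 library over 5 CpGs. AP5B1, which encodes a subunit of an endosomal adaptor complex, was at 36.98% in the control and 52.1% in the Mdivi-1 library over 22 CpGs. LOC105373383 on the X chromosome differed by 15.0 points, with 48 of 51 CpGs higher, but by 4.50 points at a minimum of 20 reads. DEGS2, a sphingolipid desaturase gene, differed by 14.8 points, and the zinc finger gene ZNF735 by 14.8 points. CLEC4GP1, RPL7AP34 and LINC00298 differed by 18.2, 15.4 and 12.9 points.

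CABCOCO1, a gene of the ciliary basal body, had the largest promoter loss (chromosome 10, 63421959 to 63422672), with 58.8% in the control and 39.6% in the Mdivi-1 library and 17 of 18 CpGs lower. Its difference was -19.2 points, with counting errors of 3.56 and 13.4 points, but pooling its reads gave -8.15 points and a minimum of 20 reads -10.4 points. PLIN2, which encodes a lipid droplet coat protein (chromosome 9, 19127818 to 19129491), was at 58.2% in the control and 42.6% in the Mdivi-1 library over 12 CpGs. RAB38, a small GTPase gene of lysosome-related organelles (chromosome 11, 87908614 to 87909233), was at 61.2% in the control and 47.5% in the Mdivi-1 library, with 19 of 20 CpGs lower. The defensin gene DEFA6 differed by -17.8 points over 5 CpGs, or -7.85 points with pooled reads. The X-linked loci LOC100420759 and LOC101928128 differed by -18.3 and -15.3 points. LOC283028, AGGF1P3, LOC100130649 and LINC02415 differed by -15.2, -14.5, -13.9 and -13.6 points, the last being -5.61 points with pooled reads. None of the 69 promoters exceeded the 95% interval for fully shared reads, but neither did any other of the 23526 measured promoters. Equal-level draws with fully shared reads gave 618 promoters, more than observed. This interval is therefore too wide to show whether a promoter lies within counting error.

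**Figure D3:**
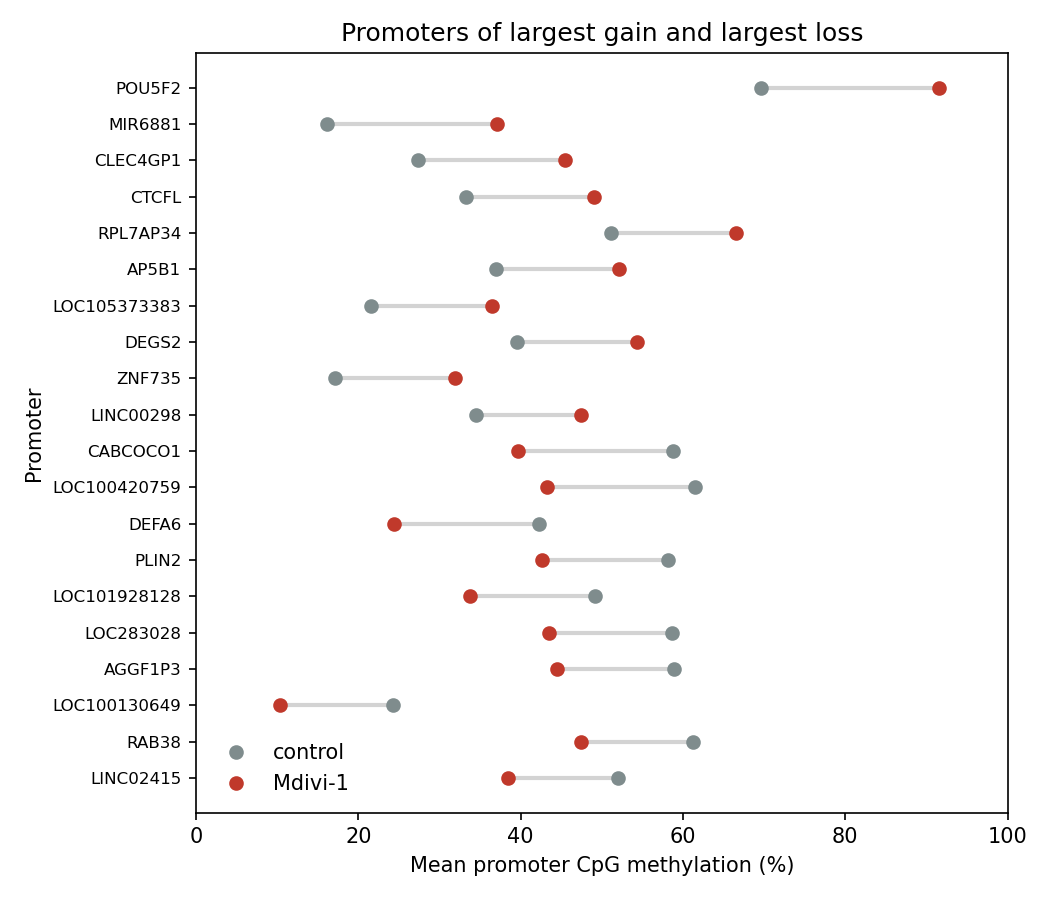
Mean promoter CpG methylation (%) of the 10 promoters of largest gain and the 10 of largest loss, with 1 point per library and a line joining the control and Mdivi-1 values. POU5F2 goes from 69.7% to 91.6% and CABCOCO1 from 58.8% to 39.6%.

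DNM1L, which encodes the fission GTPase DRP1, was examined regardless of its difference. Its promoter CpGs (chromosome 12, 32831472 to 32832083, hg19) were at 19.5% in the control and 18.7% in the Mdivi-1 library. The difference of -0.776 points over 12 CpGs was smaller than its counting error of 1.52 points for independent CpGs. Pooling its reads gave -3.74 points, more than that error and less than the 11.2 points for fully shared reads, and the deposited fractions gave -0.0689 points. The promoter was not measured at a minimum of 20 reads. Over all 68 CpGs annotated to DNM1L, the levels were 10.2% and 10.5%. The 42 intronic CpGs differed by 0.452 points and the 8 exonic CpGs by -0.548 points. The smallest two-sided Fisher p among its CpGs was 0.0687 before adjustment.

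Gene lists fixed before the data were examined were compared by their median promoter difference, placed among 10000 random lists of the same size and similar methylation. None of the 22 lists lay outside the central 95% of random lists, where 1.1 would be expected by chance. Only 1 list member, CTCFL, met the rule of size, so every other member named below is given as a value only. In each list up to 3 of the members with the largest absolute difference are named, followed in parentheses by the difference with pooled reads, with a minimum of 20 reads or with the deposited fractions where that setting turned the direction or moved the value by over 1.5 times. Pooling reads did so for 41 of 65 members chosen in this way and turned the direction of 9, so the sign of a single member depends on how reads are weighted. Of the 65 members, 59 were measured at a minimum of 20 reads. COL3A1, CTCFL, HYMAI, HOXC8, GDF15 and EIF2AK4 were not, so the lack of such a value does not make them stable. At 20 reads the medians of 13 of the 22 lists moved by over 1.5 times, none in direction, and all stayed inside the central 95%. The mean in place of the median did so for 11 lists and turned the direction of 4. It is given below only for those 4, so a list without it may still have moved in size. Of 17 measured mitochondrial fission promoters, 11 lay above and 6 below the control, with a median difference of 0.291 points at percentile 71.0; at 20 reads the median was 0.531 points, percentile 92.4. SLC25A46, an outer membrane carrier, differed by 1.54 points, MIEF1, a DRP1 receptor, by -1.27 points (-4.06 pooled, 0.707 at 20 reads) and INF2, an actin-nucleating formin, by 1.25 points. The mitochondrial fusion list had 11 measured promoters, 4 higher and 7 lower, and its median of -0.120 points lay at percentile 22.0; at 20 reads the median was -0.246 points, percentile 10.6. IMMT differed by 1.84 points (4.53 pooled), STOML2 by -1.54 points (-0.380 pooled, -0.828 at 20 reads) and MFN2, an outer membrane fusion GTPase, by -1.29 points (0.468 pooled, -2.25 at 20 reads). Among 19 mitophagy promoters the median difference was 0.129 points, percentile 44.2, with 11 members higher and 8 lower. BNIP3, a mitophagy receptor, differed by 1.59 points (-3.94 pooled, 0.232 at 20 reads), USP30 by 1.51 points (-1.30 pooled, 0.935 at 20 reads) and FKBP8 by 1.51 points (0.804 pooled, 0.0352 at 20 reads). The random fission lists spanned -0.402 to 0.705 points in their central 95%.

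For respiratory complex I, 23 of 36 promoters were higher and 13 lower, the median being 0.267 points and its percentile 81.7. NDUFB10 differed by -2.66 points (-4.82 pooled), NDUFB8 by 2.35 points (-0.385 pooled) and NDUFB11 by 2.35 points. The other respiratory chain and ATP synthase list had 41 measured promoters, 23 higher and 18 lower, and its median of 0.0386 points lay at percentile 29.4; at 20 reads the median was 0.0710 points, percentile 37.9. The mean of the list was -0.0396 points, opposite in sign to its median. SDHA, the flavoprotein of complex II, differed by -3.46 points (-0.169 pooled), COX6B2 by -2.89 points and UQCRQ by 2.07 points (-3.05 pooled). Of 19 measured mitochondrial biogenesis and mtDNA maintenance promoters, 7 lay above and 12 below the control, with a median difference of -0.0573 points at percentile 22.1; at 20 reads the median was -0.106 points, percentile 14.2. TOP1MT, the mitochondrial topoisomerase, differed by -1.46 points (-0.480 at 20 reads), MTERF1 by 0.823 points (1.33 pooled) and SIRT1 by 0.776 points (-2.71 pooled, -0.282 at 20 reads). Among 26 antioxidant defence promoters the median difference was 0.294 points, percentile 78.3, with 16 members higher and 10 lower. NQO1, a quinone reductase, differed by 4.48 points (1.78 pooled, -1.21 at 20 reads), SOD3 by 3.90 points and TXNRD1 by 3.18 points (-5.74 pooled). For calcium handling and mitochondrial transport, 18 of 26 promoters were higher and 8 lower, the median being 0.510 points and its percentile 91.1; at 20 reads the median was 0.306 points, percentile 70.3. UCP3 differed by -7.42 points (-4.72 pooled, 0.00820 at 20 reads), VDAC3, an outer membrane channel, by 5.73 points (1.12 pooled) and ATP2A3 by 3.50 points (2.11 pooled). The apoptosis list had 24 measured promoters, 19 higher and 5 lower, and its median of 0.486 points lay at percentile 87.4; at 20 reads the median was 0.157 points, percentile 41.5. CASP8, the initiator caspase of death receptors, differed by 2.39 points, XIAP by 2.30 points (9.93 at 20 reads) and FADD by -1.73 points (-5.51 pooled). Among 23 unfolded protein and integrated stress response promoters the median difference was -0.171 points, percentile 8.30, with 8 members higher and 15 lower; at 20 reads the median was -0.279 points, percentile 3.01. GDF15, a stress-induced cytokine, differed by -2.19 points (10.4 pooled), ERN1 by -1.91 points (-3.22 pooled) and EIF2AK4 by -0.915 points (-2.15 pooled, -0.431 with deposited fractions).

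Of 17 measured DNA methylation machinery promoters, 13 lay above and 4 below the control, with a median difference of 0.205 points at percentile 47.5. DNMT3B, a de novo methyltransferase, differed by 5.15 points (2.32 at 20 reads) and UHRF2 by 2.76 points (-7.30 pooled, -0.452 at 20 reads). For one-carbon and methionine metabolism, 13 of 21 promoters were higher and 8 lower, the median being 0.262 points and its percentile 70.2; at 20 reads the median was 0.439 points, percentile 90.2. MAT1A, an S-adenosylmethionine synthetase, differed by 3.43 points (2.09 pooled, 0.837 at 20 reads), AHCY by 2.56 points (0.280 pooled, 1.17 at 20 reads) and BHMT by 1.63 points (0.689 pooled). Among 26 cell cycle promoters the median difference was 0.266 points, percentile 83.0, with 17 members higher and 9 lower. CCNA1, cyclin A1, differed by 2.03 points, CDKN1C by 2.02 points (4.30 pooled, 3.97 at 20 reads) and CCND3 by 1.64 points (3.13 pooled). The housekeeping list had 20 measured promoters, 14 higher and 6 lower, and its median of 0.145 points lay at percentile 54.7; at 20 reads the median was 0.237 points, percentile 71. The mean of the list was -0.387 points, opposite in sign to its median. PGK1, a glycolytic kinase, differed by -5.73 points and SDHA by -3.46 points (-0.169 pooled).

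SH-SY5Y cultures can hold neuronal and substrate-adherent cells, and both states were represented by a list. Among 27 adrenergic (N-type) neuroblastoma promoters the median difference was 0.167 points, percentile 52.6, with 15 members higher and 12 lower. The mean of the list was -0.107 points, opposite in sign to its median. SLC18A2, the vesicular monoamine transporter, differed by -4.08 points, CHGA by -3.35 points (-5.06 pooled) and SIX3 by 2.91 points (0.573 pooled). Of 28 measured mesenchymal (S-type) neuroblastoma promoters, 18 lay above and 10 below the control, with a median difference of 0.634 points at percentile 94.0; at 20 reads the median was 0.161 points, percentile 42.0. COL3A1, a fibrillar collagen, differed by 5.79 points, MEOX1 by 4.22 points (2.30 pooled) and MEOX2 by 4.10 points (1.40 pooled). For synapse and ion channel genes, 22 of 38 promoters were higher and 15 lower, the median being 0.196 points and its percentile 50.9; at 20 reads the median was 0.309 points, percentile 64.4. KCNA1, a voltage-gated potassium channel, differed by 5.08 points and SYN2 by 4.53 points. The neurodegeneration-associated list had 29 measured promoters, 18 higher and 11 lower, and its median of 0.308 points lay at percentile 79.3. BACE1, the beta-secretase, differed by 3.88 points, ATP13A2 by 2.67 points and APOE by 2.34 points (4.02 pooled, 0.9996 at 20 reads).

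The imprinted list had 39 measured promoters, 23 higher and 16 lower, and its median of 0.212 points lay at percentile 23.7; at 20 reads the median was 0.372 points, percentile 47.7. HYMAI differed by -7.38 points (-3.36 pooled), DIRAS3, a maternally imprinted GTPase, by 5.33 points and NAP1L5 by -5.06 points. Of 22 measured germline promoters, 16 lay above and 6 below the control, with a median difference of 1.31 points at percentile 94.9. CTCFL differed by 15.8 points, MAGEC2 by -4.07 points (-1.33 pooled) and MAGEA4 by 3.79 points (2.13 pooled). For HOX clusters, 22 of 39 promoters were higher and 17 lower, the median being 0.386 points and its percentile 58.8. HOXC11 differed by 5.41 points, HOXD10 by 4.93 points and HOXC8 by -4.09 points (-1.56 pooled). Among 42 clustered protocadherin promoters the median difference was 0.671 points, percentile 50.6, with 25 members higher and 17 lower; at 20 reads the median was 1.05 points, percentile 87.5. PCDHB15 differed by -9.26 points, PCDHGC4 by -7.23 points (-4.64 pooled, -1.001 at 20 reads) and PCDHGA1 by -6.49 points (-3.53 pooled). With the mean in place of the median, the protocadherin list was at -0.120 points, percentile 2.15, which is outside the central 95% and opposite in sign to its median. It was the only list of the 22 outside, where 1.1 would be expected by chance. Random lists drew genes singly and without regard to position, so their range does not allow for promoters of 1 cluster varying together.

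The last comparison tested each CpG with a two-sided Fisher exact test on its reads, which compares these libraries and not the conditions. Of 2523690 CpGs, 10 were higher and 6 lower at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 20 points. Before adjustment 51009 CpGs, or 2.02%, had a p under 0.05, 32449 of them higher in the Mdivi-1 library. Draws at equal levels gave 1.69 to 1.71%. In 15 of the 16 CpGs, coverage relative to neighbouring CpGs was lower in the library of higher methylation by a factor under 0.8.

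The smallest p belonged to an intergenic island CpG 38530 bp from LOC442497 (chromosome 7, 461375), with 174 of 256 reads methylated in the control and 152 of 152 in the Mdivi-1 library (adjusted Fisher exact p = 2.4e-13). An exonic island CpG of DLX3, a homeobox gene (chromosome 17, 48072073), had 28 of 97 reads methylated in the control and 43 of 50 in the Mdivi-1 library (adjusted Fisher exact p = 6.4e-06). An exonic CpG of the olfactory receptor gene OR13H1 (chromosome X, 130678412) had 33 of 73 reads methylated in the control and 50 of 51 in the Mdivi-1 library. Intergenic CpGs near WDR19 (chromosome 4, 39172220) and LINC00628 (chromosome 1, 204343488) were at 78.1% and 57.3% in the control and at 100% in the Mdivi-1 library. In the other direction, an intronic island CpG of PDE4DIP, a centrosomal scaffold gene (chromosome 1, 145075505), had 101 of 187 reads methylated in the control and 104 of 447 in the Mdivi-1 library (adjusted Fisher exact p = 1.3e-07). CpGs near MIR9901 (chromosome 16, 33959437), LINC02182 (chromosome 16, 88181561) and TBX3 (chromosome 12, 115104661) differed by -58.3, -44.3 and -43.3 points. An intronic CpG of SH3BGR (chromosome 21, 40823723) differed by -53.2 points. The PDE4DIP CpG, covered 3.07 times as deeply as its neighbours in the Mdivi-1 library and 1.39 times in the control, drops out when the deepest 1 in 1000 CpGs are left out, which leaves 10 CpGs higher and 4 lower. Thinning both libraries to the lower depth ended the calls near TBX3 (adjusted Fisher exact p = 0.329) and in SH3BGR (adjusted Fisher exact p = 0.0763). Neighbours of the called CpGs within 250 bp differed in the same direction by a median of only 1.02 points. On simulated data the test called 49% of CpGs changed by 50 points at any depth and 5% of those changed by 30 points, so smaller differences were mostly not detectable at this depth.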

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

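The nuclear positions below were left out of the comparisons, as were the 70 of 74 mitochondrial positions with fractional coverage. Each set had a higher pooled level in the Mdivi-1 library than the upper bound of the control's interval. On the mitochondrial genome, 74 positions from 3952 to 9196 had a pooled level of 1.84% in the control (95% Wilson interval 1.65 to 2.07%) and 2.10% in the Mdivi-1 library (1.91 to 2.31%), so the intervals overlap. By position, 36 were higher and 32 lower. The 10728 nuclear positions left out for lack of recovered whole counts, nearly all of fractional coverage, had pooled levels of 48.7% (48.5 to 48.9%) and 49.4% (49.3 to 49.6%). These intervals cover counting error only, and no explanation was tested for either set.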

How the results depend on the processing

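The alternatives with deposited fractions, rescaled reads, fractional coverage or without the X chromosome were chosen after seeing the data. The mean difference stayed positive in each alternative, at 0.450, 0.481 and 0.487 points with minimums of 5, 20 and 30 reads, 0.526 points with pooled reads and 0.560 points with the deposited fractions, whose rounding adds to it by construction. The CpG count lay between 12 and 20 in the alternatives fixed beforehand, but was 25 with rescaled control reads and 56 with fractional coverage included. Windows numbered 686 at 20 reads, 1838 at 500 bp, 253 with at least 10 CpGs and 53 at 20 points. Promoters numbered 42 at 20 reads, 24 with at least 10 CpGs and 384 at 5 points, where 243 were higher. The cause of these changes in count was not tested. With the mean in place of the median, 1 gene list lay outside the central 95%, where 1.1 would be expected by chance, and the cause was not tested. Of the 20 named promoters, 9 were still measured at 20 reads, and of the 10 named windows 2, all in the same direction, so depth limits most of these values. No paired analysis was possible because each group has 1 library.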

Other observations

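The tests on the simulated numbers of marks were fixed before their results were seen, and the other tests in this part were chosen afterwards. Of the 16 called CpGs, 10 were at exactly 100% in 1 library. A regional methylation change is argued against for the 16 as a set, because neighbours within 250 bp moved the same way by a median of 1.02 points. It is not argued against for each CpG: the 38 neighbours of the STK32B CpG moved the same way by a mean of 9.87 points. Some CpGs had few neighbours, such as 1 near LINC00628 and 2 near MIR9901. In 93.8% of the called CpGs, the library with the higher level had under 0.8 times the relative coverage of the other, against 8.85% of 1967 other CpGs. This is consistent with reads missing or discounted in 1 library only, but no such step was observed: these CpGs have whole coverage, and sequence variants were not analysed here. Including fractional coverage raised the count to 56.

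The authors' deposited table marks 57981 positions as hyper and 44822 as hypo. Read counting at equal levels gave 91.7% as many marks as observed at positions of whole coverage, so most marks may be counting error. Of 70994 marked CpGs with at least 10 reads in both libraries, 16 passed the adjusted Fisher test. Before adjustment 30.2% had a Fisher exact p under 0.05, but these CpGs were chosen for their difference. On simulated data the adjusted test called 5% of CpGs changed by 30 points at any depth, so failing it does not show that a mark is counting error. The excess of hyper over hypo marks, a ratio of 1.29, was not reached by rounding after rescaling, which gave 1.08 in simulation (range 1.06 to 1.09). On recovered reads, with no rescaling, the ratio was still 1.21.

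The higher mean level in the Mdivi-1 library was set against 3 technical explanations, each taken as the whole cause. Less complete conversion would raise unmethylated DNA most, but windows under 5% gained 0.0410 points against 0.982 points at 80 to 95%. Windows sorted by the level of adjacent windows gained 0.233 against 0.848 points. The mitochondrial genome, also low in level, was not part of this test. Its pooled level was 1.84% in the control and 2.10% in the Mdivi-1 library, with overlapping intervals. Favoured capture or amplification of methylated molecules predicts 2.33 times as large a gain at 40 to 60% as at 85 to 95%, whereas the gain at 40 to 60% was 0.594 points, a ratio of 0.597, and 0.465 against 0.853 points with adjacent windows. Loss of methylated cytosines to conversion in the control predicts a gain in proportion to the level and was not decided: windows at 95% or more gained 0.419 points against 0.994 at 85 to 95% as sorted, 0.535 against 0.992 after thinning to equal depth, 0.694 against 0.980 with alternate CpGs and 0.748 against 0.853 with adjacent windows, so the first 3 sortings speak against it as the whole cause and the last leaves it open. Windows sorted by adjacent windows can differ in their own level from their group. The values of that sorting therefore do not give the gain at a stated level. With 1 library per group an effect of Mdivi-1 treatment cannot be told apart from a difference between any 2 cultures or libraries.

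A hypothesis that the windows meeting the rule of size belong, as a whole, to regional changes wider than 1 kb was tested through the windows next to them. Adjacent windows at 20 to 80% were measured for 386 of these windows and moved the same way by a mean of 0.556 points (95% interval 0.0748 to 1.04 points), far below the 5 points set for a shared change. A minority of wider regions is not excluded.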
